A study of Synthetic plasmid with 2 samples.

How the data were processed

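The series holds 2 libraries, 1 plasmid and 1 lentiviral, assigned to their groups by the sample type in the labels. Per the labels' protocols, plasmid DNA was purified from bacteria, cut with XhoI and joined to an adapter with a UMI before amplification. Lentivirus was filtered and concentrated by ultracentrifugation, its RNA was reverse transcribed with a primer for the viral transcript, and each cDNA received a UMI when its second strand was made, per the labels' protocols. The submitters' processing notes name Bowtie and UMI-tools for both libraries, with no version or role. Mismatch limits, UMI correction and filters are not given in the sources used here. Alignment limits could merge or split similar fragments, and template switching during amplification could join fragments of different molecules, and neither was measured in these tables.

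The values deposited by the authors are whole-number counts per barcode, not normalized. The lentiviral table names its count column a UMI count, per the file headers, and the plasmid count was read as a UMI count from the labels' protocol, so a count is called a molecule here. Each of the tables had 1 line that held column titles and no barcode and was left out. In the plasmid library 1562 barcodes stood on 2 neighbouring lines each, and their counts were summed. Entries that name an empty Bit3, a deletion in place of Bit3 or an asterisk in place of a fragment were kept as barcodes, because the sources used here do not define them. The depth was 38123633 molecules in the plasmid table and 111000198 in the lentiviral table, with counts from 1 to 289 and from 1 to 12481.

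With 1 library per group no test between groups, no p-value and no SD over replicates could be given. Shares of molecules have exact Clopper-Pearson 95% intervals, which cover counting error and not the variation of library preparation. Values were computed in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Numba 0.67.0, and plots were drawn with Matplotlib 3.10.9. Numbers of barcodes were given with the bias-corrected Chao1 lower bound and Good-Turing coverage, and evenness with the Gini coefficient, the inverse Simpson number in its unbiased form and the share of the most abundant 1% of barcodes. These were set beside Poisson draws from as many equally abundant barcodes as the Chao1 bound gives. Sharing among founder cells was computed for 100 to 500000 cells with 1 barcode each, from observed frequencies, from the unbiased pair probability, and in 20 simulated draws. The viral index was part of a lentiviral barcode in these results and was ignored wherever the libraries were compared, since the plasmid table names none.

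Overlap was compared with 20 random splits of each library into parts of equal size and with the Good-Turing coverage. Fragment use was the share of molecules with each fragment, compared as a log2 ratio of lentiviral over plasmid share. Pairs of fragments were compared with the product of their shares, for pairs with at least 50 expected molecules, beside the SD that 20 shuffles gave. A match ratio was the probability that a pair of molecules carries the same label, over the product of the fragments' own match probabilities. Its standard error came from a jackknife over 10 groups of Bit1 fragments. The designs above, apart from the match ratio and the reference of independent fragments, were fixed before the data were examined.

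The barcodes named were the 5 with the most molecules in each library. For each fragment position the text names the 3 fragments with the highest and the 3 with the lowest log2 ratio among those with at least 1000 molecules in each library, and the most and least used plasmid fragment under the same minimum. This rule was also fixed before the data were examined, and items named outside it are said to be chosen afterwards. Alternatives fixed in advance were minimums of 2 and 5 molecules per barcode, the lentiviral library thinned to the plasmid depth, leaving out the 100 most abundant barcodes, counting each barcode a single time, the unbiased pair probability, and correlations over barcodes in either library with pseudocounts of 1 and 0.5. Restrictions to 3-fragment barcodes, and to Index3 among them, were added after the data were seen. GC content was not analysed here, because the tables give fragments by number and their sequences were not used here.

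The calculations were tested on a simulated plasmid library of 38123633 molecules. A pool built from 2000000 joined Bit1-Bit2 pairs and 50000000 assembled molecules gave estimates of 1926540 and 50111640. The Chao1 bound was 34239134 for 35849192 distinct barcodes. A second draw of the same pool found 68.2% of molecules listed, as did the Good-Turing coverage of 68.2%. A separately assembled pool found 29.3%, as independent fragments did, and the whole-barcode match ratio was 2.48 for the same pool and 0.999 for the separate pool.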

Results

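STICR is a barcode library for lineage tracing, in which a lentivirus carries a barcode into a progenitor cell and the progeny of that cell inherit it. The series title names human cortical progenitors as the cells under study, and the samples analysed here are the barcode libraries themselves. A barcode was a combination of 3 numbered fragments, named Bit1, Bit2 and Bit3, with 500 numbered fragments at each position and therefore 125000000 possible combinations. The plasmid library was plasmid DNA grown in bacteria, and the lentiviral library was viral RNA from lentivirus made from a plasmid library. There was 1 library per group, so no value had a replicate and no test between groups was made. The plasmid table held 38123633 molecules and the lentiviral table held 111000198, each molecule counted by its unique molecular identifier (UMI). Intervals are exact 95% Clopper-Pearson intervals and cover counting error only. The lentiviral table gave each barcode a viral index (Index1, Index3 or IndexE), and 99.6% of its molecules carried Index3. The plasmid table named no index for its barcodes, and the labels state none for its pool. The deposited tables are designated E for the plasmid library and 3 for the lentiviral library.

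The first question was how many barcodes each library held. The plasmid library listed 23654793 distinct barcodes with 1.61 molecules per barcode, and the lentiviral library listed 33603070 with 3.30. Barcodes that named all 3 fragments accounted for 23653094 plasmid barcodes, or 18.9% of the possible combinations, and for 33318644 lentiviral combinations, or 26.7%. Every numbered Bit1 and Bit2 fragment was seen in both libraries, and 499 of the 500 Bit3 fragments were. Bit3_F_010 was the fragment absent from both. In the plasmid library 62.2% of barcodes were seen in a single molecule, against 32.6% in the lentiviral library. The Chao1 lower bound on the number of barcodes in the sampled pool was 43227344 for the plasmid library and 41947857 for the lentiviral library. The Good-Turing coverage, the share of the pool's molecules whose barcode was already listed, was 61.4% for the plasmid library and 90.1% for the lentiviral library. Thinned to the plasmid depth, the lentiviral library listed 20889312 barcodes, with a Chao1 bound of 35096009 and a coverage of 68.95%, so the higher number listed for the lentiviral library was not kept at equal depth.

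The second question was how evenly the barcodes were represented. Nearly all barcodes in both libraries were rare, with a median of 1 molecule in the plasmid library and 2 in the lentiviral library. The Gini coefficient was 0.276 in the plasmid library and 0.433 in the lentiviral library. Equally abundant barcodes, drawn by Poisson counting at the same depth, gave 0.234 and 0.288. Thinned to the plasmid depth, the lentiviral library had a Gini coefficient of 0.321, so most of the difference between the libraries went with depth. The most abundant 1% of barcodes held 3.97% of plasmid molecules and 5.99% of lentiviral molecules, where equal abundance gave 2.94% and 2.76%, and the thinned lentiviral library gave 4.82%. The effective number of barcodes, the inverse of the probability that a pair of molecules shares a barcode, was 30828666 in the plasmid library and 11609032 in the lentiviral library. The lentiviral value rested on a small number of barcodes, since it was 21247939 without the 100 most abundant barcodes of the library. The plasmid value rested on rare barcodes, and the order of the libraries turned with a minimum of 5 molecules per barcode, which gave 586060 and 3524156.

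The most abundant plasmid barcode joined Bit1_F_209 and Bit2_F_446 with a deletion in place of Bit3. It had 289 molecules, or 0.000758% of the library (0.000673% to 0.000851%), and was absent from the lentiviral table. The next plasmid barcodes all named 3 fragments. Bit1_F_447-Bit2_F_226-Bit3_F_336 had 37 molecules, Bit1_F_228-Bit2_F_073-Bit3_F_031 had 34, Bit1_F_246-Bit2_F_178-Bit3_F_497 had 32 and Bit1_F_094-Bit2_F_450-Bit3_F_336 had 29. Equal abundance gave a highest count of 11 in the plasmid library and 15 in the lentiviral library. The 5 most abundant lentiviral barcodes all carried a minor index. The first was Bit1_F_246-Bit2_F_178-Bit3_F_497 with IndexE, which had 12481 molecules, or 0.0112% of the library (0.0110% to 0.0114%). Bit1_F_467-Bit2_F_414-Bit3_F_486 followed with 11194 molecules and Bit1_F_174-Bit2_F_330-Bit3_F_124 with 6623, both with Index1. Bit1_F_287-Bit2_F_028-Bit3_F_339 with IndexE had 5640 molecules and Bit1_F_409-Bit2_F_258-Bit3_F_154 with Index1 had 5550. The highest count of any Index3 barcode was 186.

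**Figure D1:**
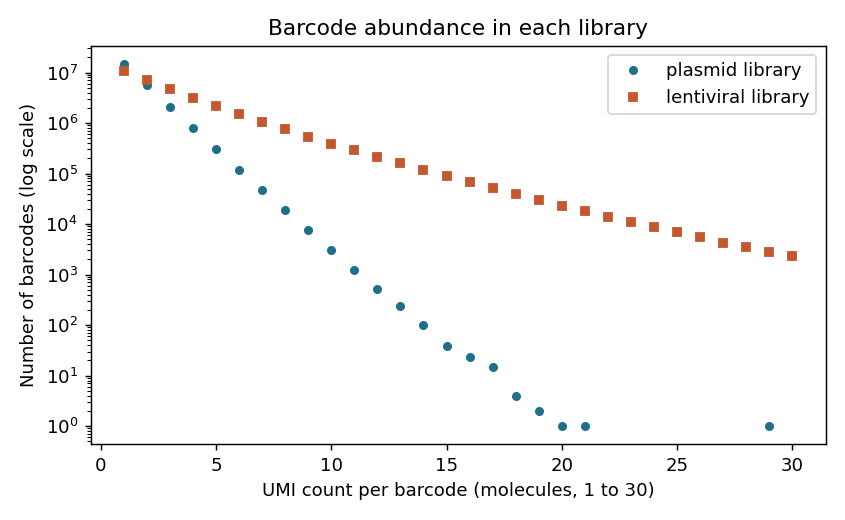
Number of barcodes (y axis, log scale) at each UMI count per barcode in molecules (x axis, 1 to 30), for the plasmid library (circles) and the lentiviral library (squares). The plasmid library had more barcodes at 1 molecule (14721463 against 10957956), and barcodes above 30 molecules lie outside the plotted range.

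The third question, set by the use of such a library, was how often founder cells would share a barcode by chance if each received 1 barcode drawn from the library. At the observed barcode frequencies, 0.584% of 100000 founder cells would share their barcode with another founder in the plasmid library and 0.618% in the lentiviral library. With 10000 founder cells the shares were 0.0586% and 0.0832%, and with 500000 they were 2.87% and 2.80%. In 20 simulated draws of 100000 founder cells the mean share was 0.577% for the plasmid library and 0.614% for the lentiviral library. Observed frequencies overstate sharing where most barcodes are seen in 1 molecule. The unbiased probability that a pair of molecules shares a barcode gave 0.324% of 100000 founder cells in the plasmid library. In the lentiviral library it gave 0.858%, a value that weights the very abundant barcodes fully at every number of founder cells. For 500000 founder cells it gave 1.61% and 4.22%. Both lentiviral values lie above those at observed frequencies, 0.618% and 2.80%, which themselves overstate sharing. They are therefore overstated, and the gap between the libraries by this measure does not show that sharing would differ that much. At observed frequencies, the order at 100000 founder cells turned without the 100 most abundant barcodes. Then 99.4419% of founder cells had a barcode of their own in the lentiviral library and 99.4165% in the plasmid library. The order also turned with minimums of 2 and 5 molecules per barcode, when 99.3% and 98.3% had their own in the lentiviral library and 98.7% and 81.6% in the plasmid library. At equal depth it was kept, with 99.2% in the thinned lentiviral library and 99.4% in the plasmid library. The effective number behind the unbiased probability kept its order without those 100 barcodes, at 30897526 in the plasmid and 21247939 in the lentiviral library. It did so too with a minimum of 2 (11616584 and 9430079), and turned with a minimum of 5 (586060 and 3524156).

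**Figure D2:**
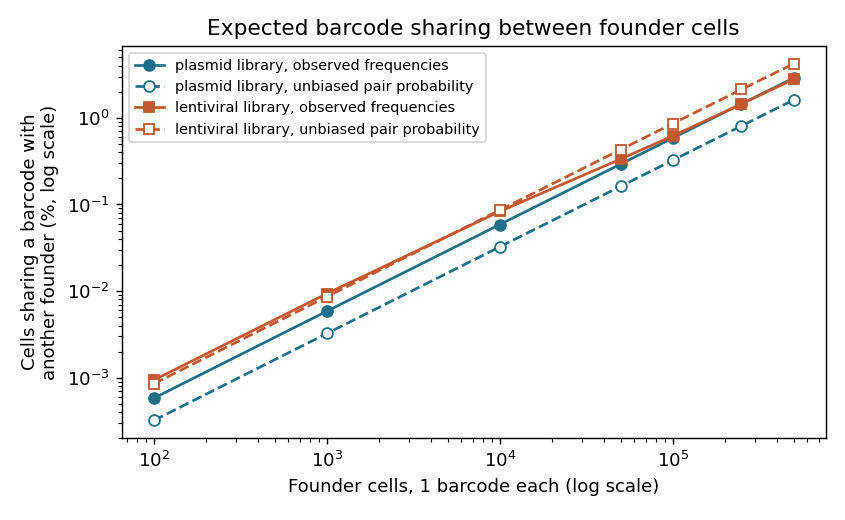
Expected percent of founder cells sharing a barcode with another founder (y axis, log scale) against the number of founder cells with 1 barcode each (x axis, log scale), for the plasmid library (circles) and the lentiviral library (squares). Filled symbols use observed barcode frequencies and open symbols the unbiased pair probability, which at 100000 founder cells gave 0.324% and 0.858%. The lentiviral 0.858% lies above the 0.618% at observed frequencies and overstates sharing.

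The fourth question was how far the barcodes of the plasmid library were found again in the lentiviral library. Ignoring the index, 10230338 barcodes were listed in both tables. They made up 43.2% of plasmid barcodes and 30.5% of lentiviral barcodes, and held 45.7% of plasmid molecules and 35.1% of lentiviral molecules (35.120% to 35.138%). The order of the libraries turned at equal depth. With the lentiviral library thinned to the plasmid depth, 6730570 barcodes were in both tables, as 28.5% of plasmid and 32.3% of lentiviral barcodes, and they held 30.5% of plasmid and 35.1% of lentiviral molecules. A further draw of molecules from the plasmid pool would be expected to find its barcode listed for 61.4% of molecules, the Good-Turing coverage. Random parts of equal size of the plasmid library shared barcodes for 41.4% of molecules, and such parts of the lentiviral library for 78.1%. Each part was searched in another part, which is shallower than the full table. These shares are therefore lower than full tables would give, and the coverage is the closer reference. A reference chosen after the data were seen drew the 3 fragments of a barcode independently, each at its own frequency. Among 3-fragment barcodes, 35.67% of Index3 molecules had a barcode listed for the plasmid library, where independent fragments gave 35.50%. By distinct barcode the values were 30.71% and 30.80%, and both small differences exceeded counting error. The reference by distinct barcode can draw a combination more than a single time, which a list of distinct barcodes cannot. The difference by distinct barcode therefore does not measure a departure from independence. For Index1 molecules the observed share was 35.6% (35.5% to 35.8%) and the independent value 33.2%, although 11 barcodes held 11% of these molecules. By distinct barcode Index1 gave 33.95% against 34.12%, with no excess. For IndexE molecules the observed share was 86.2% (85.8% to 86.5%) and the independent value 25.8%, although 7 barcodes held 79.3% of these molecules. By distinct barcode IndexE gave 36.9% (35.4% to 38.4%) against 34.1%. The share of lentiviral molecules listed for the plasmid library was 16.1% when barcodes with fewer than 2 molecules were left out of both tables.

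**Figure D3:**
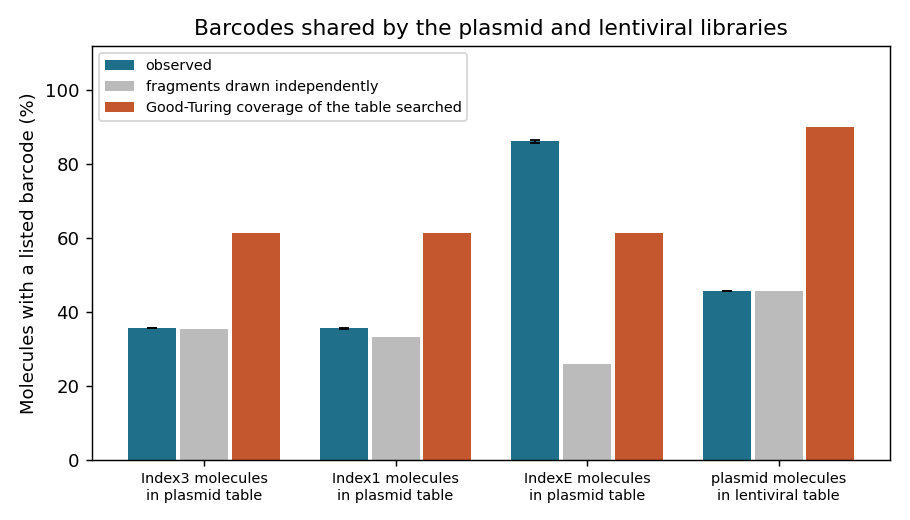
Percent of molecules whose 3-fragment barcode was listed in the other library's table (y axis), by viral index and for plasmid molecules (x axis), with 95% counting intervals on the observed bars. Index3 molecules stood at 35.7% beside 35.5% for independently drawn fragments (grey) and 61.4% for the Good-Turing coverage of the plasmid table (orange).

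Counts of single barcodes were nearly uncorrelated between the libraries. With median counts of 1 and 2 molecules per barcode, counting limits such a correlation. The low values therefore do not show that the abundances themselves were unrelated. Across the barcodes listed in both tables, Pearson's r of log2 counts was 0.068 and Spearman's rho 0.062. Barcodes are not independent replicates, so no p-value was computed. Random parts of equal size of the plasmid library correlated with a Spearman's rho of 0.128, and those of the lentiviral library with 0.398. These parts were shallower than the full tables, so their values are no upper limit for the comparison. When barcodes listed in either table entered, with absence counted as 0, rho was −0.406.

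Single fragments had many more molecules each than single barcodes, so their shares were far less limited by counting. Across fragments with at least 1000 molecules in each library, Pearson's r of the log2 shares was 0.772 over 499 Bit1 fragments, 0.788 over 500 Bit2 fragments and 0.95 over 492 Bit3 fragments. The SD of the log2 ratio was 0.416 for Bit1, 0.732 for Bit2 and 0.678 for Bit3. The higher r of Bit3 thus did not mean smaller shifts than for Bit1. Log2 plasmid shares also spread more widely for Bit3, with an SD of 1.15 against 0.430 for Bit1 and 0.595 for Bit2. Fragments are not independent replicates either. Use was least even for Bit3, where the coefficient of variation over fragments was 0.711 in the plasmid library and 1.06 in the lentiviral library. For Bit1 it was 0.256 and 0.397, and for Bit2 it was 0.359 and 0.567. The difference between the libraries was smaller with a minimum of 5 molecules per barcode, which gave 0.465 and 0.560 for Bit1, 0.685 and 0.726 for Bit2, and 1.46 and 1.503 for Bit3. With each barcode counted a single time, the values were 0.219 and 0.264 for Bit1, 0.304 and 0.434 for Bit2, and 0.613 and 0.722 for Bit3. Counting alone gave 0.00362 in the plasmid library and no more than 0.00214 in the lentiviral library. The spread of log2 shares was 1.5 times wider in the lentiviral library for Bit1, 1.85 times for Bit2 and 1.45 times for Bit3. The lentiviral share was at least 2-fold lower than the plasmid share for 18 Bit1, 90 Bit2 and 88 Bit3 fragments, and at least 2-fold higher for 0, 7 and 12.

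Bit3_F_138 had the highest lentiviral to plasmid ratio among fragments with at least 1000 molecules in each library. It held 0.0152% of plasmid molecules (0.0148% to 0.0156%) and 0.213% of lentiviral molecules (0.212% to 0.214%), a 14-fold difference. Bit3_F_489 followed with a log2 ratio of 1.64 and Bit3_F_063 with 1.59, the latter with 1.15% of lentiviral and 0.383% of plasmid molecules. The lowest Bit3 ratios were −2.23 for Bit3_F_429, −2.03 for Bit3_F_146 and −1.95 for Bit3_F_400. Bit3_F_429 was also the fragment with the fewest plasmid molecules under the minimum, at 0.00703%. The size of these ratios depended on how rare barcodes were counted. The log2 ratio of Bit3_F_138, 3.81 over all molecules, was 5.74 and 9.94 with minimums of 2 and 5 molecules per barcode. With a minimum of 5 the plasmid library held 2858320 molecules in all. The ratio of 9.94 thus rests on few plasmid molecules of Bit3_F_138, fewer than the 1000 required for naming a fragment. The log2 ratio of Bit3_F_063 was 0.58 with each barcode counted a single time. Bit3_F_456, the most used Bit3 fragment of the plasmid library, held 0.826% of plasmid and 0.594% of lentiviral molecules. Its log2 ratio of −0.48 was −1.91 with a minimum of 5 molecules per barcode.

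Among Bit2 fragments the highest log2 ratios were 1.63 for Bit2_F_268, 1.27 for Bit2_F_262 and 1.21 for Bit2_F_331. The ratio of Bit2_F_262 was 2.34 and 5.97 with minimums of 2 and 5 molecules per barcode. With a minimum of 5, that of Bit2_F_268 was 2.59 and that of Bit2_F_331 was 2.14. The lowest ratios over all molecules were −2.34 for Bit2_F_248, −2.21 for Bit2_F_105 and −2.05 for Bit2_F_102. With a minimum of 5, that of Bit2_F_105 was −2.91. Bit2_F_248 held 0.0833% of plasmid molecules (0.0824% to 0.0842%) and 0.0164% of lentiviral molecules (0.0162% to 0.0167%). The most used Bit2 fragment of the plasmid library, Bit2_F_047, held 0.489% of plasmid and 0.471% of lentiviral molecules, a log2 ratio of −0.05 that was −0.90 with a minimum of 5 molecules per barcode. The least used, Bit2_F_415, had 0.0177% and 0.0163%, and the sign of its difference turned when rare barcodes were left out or each barcode was counted a single time. Bit1 ratios spanned the narrowest range. They reached 0.87 for Bit1_F_285, 0.80 for Bit1_F_324 and 0.71 for Bit1_F_122, and the lowest were −1.75 for Bit1_F_368, −1.39 for Bit1_F_101 and −1.32 for Bit1_F_406. The ratio of Bit1_F_285 was 1.62 with a minimum of 5 molecules per barcode. That of Bit1_F_368 was −1.14 with each barcode counted a single time. Bit1_F_200, the most used Bit1 fragment of the plasmid library, held 0.360% and 0.352%, and Bit1_F_417, the least used under the minimum, held 0.0289% and 0.0361%.

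**Figure D4:**
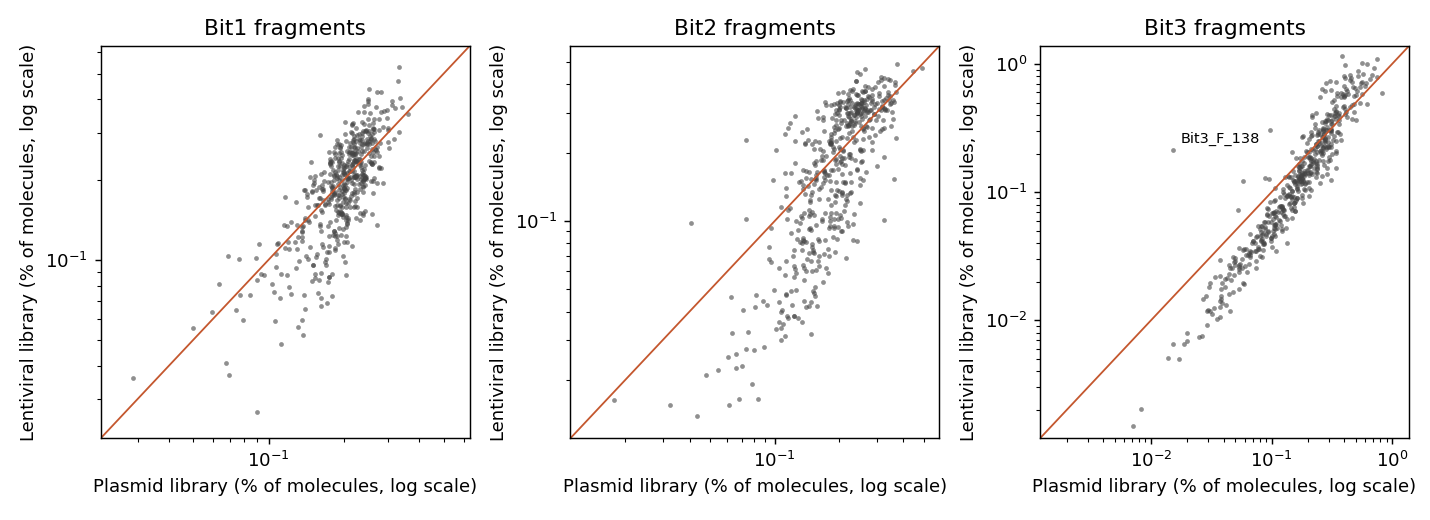
Share of lentiviral molecules (y axis, percent, log scale) against share of plasmid molecules (x axis, percent, log scale) for each Bit1, Bit2 and Bit3 fragment with at least 1000 molecules in both libraries, 1 point per fragment. The line marks equal shares, and Bit3_F_138 lies above it at 0.0152% and 0.213%.

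The last question was whether the fragments of a barcode were joined at random. Over all molecules, Bit1-Bit2 pairs departed most from independence. Over pairs with at least 50 expected molecules, the SD of observed over expected molecules was 0.401 in the plasmid library, where counting alone gave 0.0870. The Bit1-Bit3 and Bit2-Bit3 values were 0.114 and 0.157, with 0.0882 and 0.0886 from counting. In the plasmid library 4262 of 239260 Bit1-Bit2 pairs had at least 2 times the expected molecules, 20257 had at most 0.5 times, and 48 were not seen. In the lentiviral library the SD was 0.605 for Bit1-Bit2, 0.180 for Bit1-Bit3 and 0.230 for Bit2-Bit3, with 0.0633, 0.0702 and 0.0713 from counting. The lentiviral Bit1-Bit2 value was 0.393 without the 100 most abundant barcodes. With a minimum of 5 molecules per barcode the lentiviral order turned, with 0.521 for Bit1-Bit2, 0.495 for Bit1-Bit3 and 0.581 for Bit2-Bit3. No counting reference was computed for this setting, in which each barcode adds at least 5 molecules to its pair. How much of these values was counting error was therefore not measured.

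The Bit1-Bit2 departures were not shared by the libraries, with a Pearson's r of 0.0054 between the pair ratios of the plasmid and lentiviral libraries across 235564 pairs. For Bit1-Bit3 pairs r was 0.0018, and for Bit2-Bit3 pairs it was 0.303. The pair of Bit2_F_425 and Bit3_F_033 had 3.14 times its expected molecules in the plasmid library and 3.19 times in the lentiviral library. The pair of Bit2_F_105 and Bit3_F_326 had 5 molecules against 316 expected in the plasmid library and 6 against 206 in the lentiviral library. The pair of Bit1_F_041 and Bit2_F_190 was not seen in either library, where 181 and 546 molecules were expected. These pairs were chosen after their values were seen, as those highest or lowest in both libraries.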

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

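All tests of explanations in this part were chosen after the results were seen. The 4 signals given here are listed because they came from minor indices or incomplete barcodes, which the labels do not describe.

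In the lentiviral library 0.357% of molecules (0.356% to 0.358%) carried Index1 and 0.0311% (0.0308% to 0.0314%) carried IndexE, as 396611 and 34540 molecules. Among Index3 molecules 1.595% (1.593% to 1.598%) named no Bit3, against 0.00530% of plasmid molecules (0.00507% to 0.00553%), a 301-fold difference. The other indices had such molecules too, with 1.52% of Index1 and 0.272% of IndexE molecules. In the plasmid library the barcode of Bit1_F_209 and Bit2_F_446 with a deletion in place of Bit3 had 289 molecules, 99.7% of all plasmid molecules with such a deletion. The same Bit1-Bit2 pair had 82 molecules with 3 fragments, of which the most abundant barcode had 3.

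The minor indices held a few barcodes with very many molecules. With at least 100 molecules each, 7 IndexE barcodes held 79.3% of the 3-fragment IndexE molecules and 11 Index1 barcodes held 11% of those of Index1. Index3 barcodes read with a wrong index are argued against, because these barcodes had a median of 2 molecules under Index3, with 1 for those of IndexE and 4 for those of Index1, and none had more than 10. A random draw from the plasmid pool is argued against for IndexE, because its most abundant barcode had 12481 molecules where its plasmid share predicted 0.0280, a ratio of 445498. Single clones carried into both preparations may account for the IndexE barcodes, whose median plasmid count was 9, but not for those of Index1, whose median plasmid count was 0. Where the Index1 barcodes came from stayed open, and no biological explanation was tested because the design names only the kind of library.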

How the results depend on the processing

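The restrictions to 3-fragment barcodes and to Index3, and the ratio of the observed overlap to that of independent fragments, were chosen after the data were seen. A value counted as kept when it stayed within its counting interval, within 1.5 times for a number of barcodes, or equal to 2 decimals for a coefficient. Among the leading results 40 alternative values were kept, 42 moved and 1 changed sign, and among the other results 199 were kept, 178 moved and 5 changed sign. For the 23 named fragments, 3 of 161 alternative log2 ratios had the other sign, all of them for Bit2_F_415. The ratio itself moved by over 1.5 times in 15 of the 161, of which 10 were with a minimum of 5 molecules, 2 with a minimum of 2 and 3 with each barcode counted a single time, so the sizes were less stable than the signs. No paired analysis was possible because each group had 1 library, and leaving out a replicate was not possible for the same reason. The comparison with GC content was not run.

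With a minimum of 2 molecules per barcode the plasmid library listed 8933330 barcodes, with an effective number of 11616584. Of 100000 founder cells 98.7% had a barcode of their own in the plasmid library and 99.3% in the lentiviral library, and the overlap was 16.1% of lentiviral molecules. Spearman's rho between libraries was 0.0534, r for Bit2 shares was 0.778, the SD over Bit1-Bit2 pairs was 0.466 and 0.513, and the log2 ratio of Bit2_F_415 was 0.14.

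With a minimum of 5 the libraries listed 505700 and 7549618 barcodes, with effective numbers of 586060 and 3524156, and 81.6% and 98.3% of founder cells had a barcode of their own. The overlap was 1.70%, which was 1.04 times that of independent fragments, and rho was 0.0259. This overlap includes 6 very abundant IndexE barcodes with 6 to 32 plasmid molecules each, and the ratio without them was not computed. The r of fragment shares was 0.718, 0.735 and 0.824 for Bit1, Bit2 and Bit3, the SD over Bit1-Bit2 pairs was 0.578 and 0.521, and Bit2_F_415 had a log2 ratio of 0.46. Both minimums remove barcodes by depth, and the plasmid library, with 1.61 molecules per barcode, lost a larger share of its barcodes.

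Thinned to the plasmid depth, the lentiviral library listed 20889312 barcodes, 99.2% of founder cells had their own, and rho was 0.0501. Without the 100 most abundant barcodes the lentiviral effective number was 21247939, 99.4419% of founder cells had their own barcode, and the SD over Bit1-Bit2 pairs was 0.393. With Index3 alone these were 21682949, 99.4494% and 0.392, the overlap was 35.7%, and its ratio to independent fragments was 1.00466. The barcodes left out in both settings include the very abundant ones of Index1 and IndexE. With 3-fragment barcodes of any index the overlap was 35.6844%.

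With each barcode counted a single time, r of fragment shares was 0.803, 0.797 and 0.963, the SD over Bit1-Bit2 pairs was 0.327 and 0.261, and Bit2_F_415 had a log2 ratio of 0.25. The unbiased pair probability gave 99.7% and 99.1% of founder cells with their own barcode, and its lentiviral value overstates sharing, as given with the founder cells. Over barcodes in either library, rho was −0.406 and Pearson's r −0.360 with a pseudocount of 1 and −0.417 with 0.5. That setting adds barcodes that are absent from 1 table by construction, which lowers a correlation. For the other changes of value the cause was not tested.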

Other observations

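All tests in this part were chosen after the results were seen. The minor indices differed in make-up. The 156329 3-fragment Index1 barcodes used 10346 Bit1-Bit2 pairs, or 4.14% of the possible pairs, where Index3 used 99.1% and the plasmid library 99.6%. These shares were not at equal depth, with 390560 Index1 molecules, 108803729 of Index3 and 38121324 in the plasmid library. Without any barcode on the Bit1-Bit2 pair of a very abundant one, 156316 Index1 barcodes remained. Their effective number of joined Bit1-Bit2 molecules was 3404 ± 69.6 (jackknife SE), and that of assembled molecules was 164098 ± 2513. The first is the inverse of the excess of the pair match probability over that of independent fragments. The second is the same for whole barcodes, over Bit3 added independently to the pairs. IndexE used 861 pairs, and it was the one index with asterisk entries, 71 barcodes with 3.10% of its molecules.

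By molecule, Index3 barcodes were found in the plasmid library slightly more often than independently drawn fragments would be. The shares were 35.67% and 35.50%, a difference beyond counting error. A plasmid table too shallow to list its pool is argued against, because 35.6692% of Index3 molecules had a listed barcode where the coverage of the plasmid table was 61.4%. Complete exchange of fragments between molecules during preparation of the lentiviral library is argued against, because the Bit1-Bit2 match ratio within Index3 was 1.06 ± 0.0013 (jackknife SE). Exchange in part of the molecules of the deposited pool is argued against too, because the pairs it left intact would match those of the plasmid library, and that Bit1-Bit2 ratio was 1.00086 ± 0.00015. A candidate explanation is that the Index3 molecules came from a pool assembled apart from the one in the plasmid table with the same fragments, since the whole-barcode match ratio between them was 1.0026 ± 0.00025, against 2.23 ± 0.012 within the plasmid library. The designations E and 3 of the deposited tables are the characters that end IndexE and Index3. Between the plasmid library and Index3 the pair match ratio was highest for Bit2-Bit3, at 1.00166 ± 0.00009, with 1.00012 ± 0.00006 for Bit1-Bit3. The small excess of the whole-barcode ratio over 1 thus went with shared pairs, Bit2-Bit3 most of all, and why these were shared stayed open.

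Over all molecules, Bit1-Bit2 pairs were used less evenly than other pairs. The order turned in the lentiviral library with a minimum of 5 molecules per barcode, a setting without a counting reference. Counting error is argued against, because the SD over pairs in the plasmid library was 4.61 times that of counting. Joining or reading that depends on sequence is argued against as the whole cause, because the pair ratios of the plasmid library and Index3 had an r of 0.0067, although it stays open for single pairs such as Bit1_F_041 with Bit2_F_190. A limited number of joined Bit1-Bit2 molecules before Bit3 was added may account for it, since Index3 molecules without Bit3 matched those with Bit3 in their Bit1-Bit2 pair with a ratio of 1.06 ± 0.0015, but loss of Bit3 from complete barcodes would give the same. If all excess matching came from a limited number of joined molecules, their effective number was 1871158 ± 20317 in the plasmid library and 2640863 ± 51535 in Index3. It estimates joined molecules, so it can exceed the 250000 possible pairs. No biological explanation was tested for either pattern.

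Bit2-Bit3 departures were partly shared by the plasmid library and Index3, with an r of 0.405 between their pair ratios, against 0.0067 for Bit1-Bit2. Components were computed for Bit2-Bit3 pairs only, with no reference value. The first component held 32.4% of the squared deviation in the plasmid library and 39.0% in Index3. Its loadings correlated between them with an r of 0.967 across Bit2 fragments and 0.976 across Bit3 fragments. The pair of Bit2_F_105 and Bit3_F_474, chosen after its values were seen, had 0 molecules in both, against 92.3 and 41.5 expected.

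A hypothesis for IndexE is that its remaining barcodes share joined Bit1-Bit2 molecules with the plasmid library. These were the 3671 left of 3814 once all barcodes on the Bit1-Bit2 pair of a very abundant one were left out. Their Bit1-Bit2 match ratio with the plasmid library was 1.11 ± 0.034, beside 1.11 ± 0.0012 within the plasmid library, which is consistent with it. Their ratio with Index3 was 1.028 ± 0.044, and the difference of 0.0794 ± 0.049 between these ratios was under 2 SE, so a tie to the plasmid library rather than to Index3 was not shown. Given a shared pair, their whole barcodes matched those of the plasmid library with a ratio of 0.990 ± 0.026, against 2.01 within that library, and those of Index3 with a ratio of 1.101 ± 0.022, a difference of −0.111 ± 0.021 toward Index3. For whole barcodes without that condition the ratio was 1.132 ± 0.054 with Index3 and 1.097 ± 0.032 with the plasmid library. Their difference of −0.0351 ± 0.064 was within 1 SE, so no tie to either was shown there. The hypothesis leaves the excess with Index3 given a shared pair unexplained, and the source of that excess stayed open.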
